A study of Homo sapiens with 4 samples.

How the data were processed

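Single-cell RNA was measured in 4 libraries of cardiomyocyte spheroids from the human induced pluripotent stem cell line UCSD142i-86-1, 2 treated with 5 µM LOM612 and 2 with 0.2% DMSO for 48 hours from day 9 of differentiation. Per the labels' protocols, cells were differentiated with CHIR99021 (6 µM) and IWP4 (5 µM), inhibitors of GSK3 and of WNT secretion. The same protocols state that spheroids were dissociated with a cardiomyocyte dissociation kit, 10000 cells per sample were loaded, and libraries were made with the 10x Chromium 3′ v3 droplet kit, which reads the 3′ end of transcripts and tags each molecule with a UMI. Sequencing dates and batches are not given in the sources used here, so a batch that went with treatment cannot be told apart from it. Dissociation can itself induce stress genes, and a 3′ library does not separate isoforms.

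The deposited files hold whole-number UMI counts per gene and barcode, not normalized, for every barcode including empty droplets. Per the file headers the matrices were written by Cell Ranger 4, whereas the submitters' processing notes name Cell Ranger 6.1.1, Seurat 4.0.5 and the human genome build GRCh38 (hg38). The annotation release is not given in the sources used here. Of 36601 genes in the files, 34616 matched a gene of GENCODE release 29 by Ensembl identifier, from which coordinates were taken. No cell annotation by the authors was used.

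Cells were called in each library by an order-of-magnitude rule. The 99th percentile of UMIs over the 3000 largest barcodes was divided by 10, which gave minimums of 7685 and 7164 UMIs with DMSO and 10267 and 8332 with LOM612, and at least 1000 genes were required. This kept 7136, 6343, 5861 and 4780 barcodes in DMSO replicates 1 and 2 and LOM612 replicates 1 and 2, from 2815261, 2710001, 2687591 and 2386061 barcodes in the files. Barcodes with over 30% of UMIs from mitochondrially encoded genes were removed (44, 32, 4 and 7), and then doublets called with scrublet in scanpy (159, 135, 135 and 85). The automatic doublet limit marked 2 barcodes (0.028%) in DMSO replicate 1, so a common score limit of 0.25 was set after the data were seen, and the automatic limit became an alternative. The higher UMI minimum with LOM612 leaves out shallow cells there that would be kept with DMSO, and a common minimum was added as an alternative after the data were seen.

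Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 gave 13 clusters. Clusters were named from marker lists where at least 2 markers of the class were among the cluster's top 10 genes by fold over the median cluster (pseudocount 10 CPM) and more than those of any other class. At least 3 markers also had to reach a fold of 2 and a UMI in 25% of cells. These limits were set after the data were seen, and other clusters stayed unnamed. Genes changed by treatment were not taken out of the variable genes. Free RNA was profiled from barcodes with 100 to 400 UMIs. The share of UMIs from it was estimated from hepatocyte transcripts in cardiomyocyte-like cells (3.41%, 2.68%, 2.72% and 2.46%) and from cardiomyocyte transcripts in endoderm or hepatocyte-like cells (5.31%, 2.97%, 6.94% and 2.74%), in the order DMSO replicates 1 and 2 and LOM612 replicates 1 and 2. These are upper estimates, since a class may transcribe those genes at a low level. Subtracting it from the sums was an alternative. Cell cycle phases were called from the S and G2/M gene lists after each cell was thinned to 7000 UMIs, below every minimum, so no cell was left out.

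UMI counts were summed per library and class, since cells are not replicates. Summed UMIs in cardiomyocyte-like cells were 54442131, 40337211, 43991571 and 31479275, from 2691, 2190, 2133 and 1634 cells. A class needed 30 cells in each library. Genes were tested with edgeR's robust quasi-likelihood test on these counts after TMM scaling and the filterByExpr filter, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05, without the replicate number as a term. The difference in response between classes was tested in a fit with each library as a block. Fold changes are LOM612 against DMSO on the log2 scale. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. With an estimated correlation the test rests on the few residual degrees of freedom that 4 libraries leave, and its power was not checked. It passed 0 lists in each named class and over all cells, so not passing it does not show that a list was unchanged. Class shares and cycling shares were tested with edgeR on cell numbers, and with exact 2-sided permutation tests. With 2 libraries per group the spread of a single gene is poorly known, and edgeR moderates it across genes.

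The tests were checked on counts simulated from the libraries' sizes and the genes' means and dispersions, with 200 genes changed. The gene test recovered 28.8%, 60.6% and 82.8% of genes changed 1.3-fold, 1.5-fold and 2-fold in cardiomyocyte-like cells (18708 genes), and called 0.132% of unchanged genes. Over all cells (22615 genes) it recovered 65.6%, 66.2% and 84.8%, and called 0.0588%. The difference test (21085 genes) recovered 63.6% of genes at 2-fold and called 0.136% of unchanged ones. The list test, camera at its preset correlation, found a list raised 1.3-fold and called 0 of 36 unchanged lists. Genes were drawn independently of each other and the unchanged lists at random. The raised list was drawn from genes with a mean above the median, so finding low-count lists was not checked. Because of the independent draws, this check also does not cover lists whose members vary together, such as G2 and M phase (estimated correlation 0.77 in cardiomyocyte-like cells). At this depth, changes in single genes of 1.3-fold can be missed.

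The rule for named genes, the 37 gene lists, the cell type markers, the tests and the alternatives not listed as added were fixed before the data were examined. FOXO1, FOXO3, FOXO4, FOXO6 and FOXM1 were always named. In cardiomyocyte-like cells the 10 rising and 10 falling genes with the largest change were named, among those past the threshold with at least 10 CPM in the higher group and no overlap between groups. Clone-named, mitochondrially encoded and sex-linked marker genes were left out of that choice. From each list up to 4 members with the lowest p were open to naming, or up to 2 with the highest mean CPM where none passed, and from the sum of all cells the next 5 genes in each direction. Part of the genes open to naming are named in the text, and 2 were left out of that choice. From every other class and the difference test, the 5 genes with the lowest adjusted p were named. Leading genes of clusters were named to describe them, and genes outside the rule are said to be chosen after their values were seen.

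Alternatives were DESeq2 size factors, library totals, DESeq2's Wald test, limma-voom, no filter on low counts, a replicate term, leaving out each library, other limits on mitochondrial share, UMIs and doublets, thinning, leaving out mitochondrial and ribosomal protein genes, a test against a 1.2-fold change, G1 cells alone, Leiden resolution 1.0, and cells with a TNNT2 UMI. Added after the data were seen were the automatic doublet limit, the common UMI minimum, free RNA subtraction, each cardiomyocyte-like cluster alone and each other class against cardiomyocyte-like cells. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, umap-learn 0.5.12 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.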

Results

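The series holds single-cell RNA counts from 4 libraries of cardiomyocyte spheroids grown from the human induced pluripotent stem cell line UCSD142i-86-1. Spheroids at day 9 of differentiation were kept for 48 hours with 5 µM LOM612, a small molecule that the series describes as a FOXO activator, or with 0.2% DMSO as the control. The DMSO share in the LOM612 wells is not given in the sources used here, so a difference in vehicle is part of what the comparison may hold. FOXO proteins are transcription factors that are held in the cytoplasm when insulin and growth factor signalling is active. Each treatment had 2 libraries, named replicates 1 and 2. No label says that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The comparison asks which transcripts, and which cell classes, differed between spheroids with and without LOM612.

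The DMSO libraries held 195135755 and 159706386 unique molecular identifiers (UMIs) over all barcodes, and the LOM612 libraries 182352653 and 140693690. After filtering, 6933 and 6176 cells remained with DMSO and 5722 and 4688 with LOM612. The median UMI count per cell was 17294 and 16717.5 with DMSO and 19322 and 18513.5 with LOM612, and the median number of genes was 4563 and 4530.5 against 4877 and 4768. The median share of UMIs from mitochondrially encoded genes was 5.18% ± 0.27 (SD, n = 2) with DMSO and 4.16% ± 0.15 with LOM612. With 2 libraries against 2 the exact 2-sided permutation test cannot go below p = 0.333, the value it gave here. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 10.5 for DMSO and 4.43 for LOM612 in cardiomyocyte-like sums.

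The spheroids held cardiomyocyte-like cells together with several other cell classes. Clusters led by MYH6, TTN and MYL3, genes of the contractile apparatus, were cardiomyocyte-like. Clusters led by WT1 with TBX18 or TCF21 were epicardial-like, those led by LUM, DCN and COL3A1 fibroblast or mesenchymal-like, that led by AFP, SERPINA1 and APOA2 endoderm or hepatocyte-like, and that led by PLVAP, EMCN and KDR endothelial-like. Cardiomyocyte-like cells made up 37.1% ± 2.37 (SD, n = 2) of cells with DMSO and 36.1% ± 1.71 with LOM612. Epicardial-like cells made up 19.8% ± 1.64 and 21.3% ± 0.0603, and fibroblast or mesenchymal-like cells 14.0% ± 0.710 and 14.8% ± 0.220. Endoderm or hepatocyte-like cells made up 7.34% ± 0.533 and 8.29% ± 0.770, and endothelial-like cells 1.48% ± 0.170 and 1.5% ± 0.320. Clusters 2, 6, 11 and 12 stayed unnamed under naming limits set after the data were seen. They held 13.3%, 6.32%, 0.420% and 0.176% of cells with DMSO and 12.7%, 4.61%, 0.471% and 0.240% with LOM612, and cluster 2 was led by DKK1, SHOX2 and TRH.

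The share of cells passed the edgeR test in 0 of 9 classes, and no exact permutation p was below 0.333. The lowest adjusted p was 0.105, for unnamed cluster 6, led by the proliferation genes TOP2A, CENPF and MKI67, the single class with an unadjusted edgeR p under 0.05 (0.0116). That cluster held 6.32% ± 0.0629 of cells with DMSO and 4.61% ± 0.444 with LOM612 (SD, n = 2). Its leading genes are themselves cell cycle genes, whose S phase and G2 and M phase lists were lower in the sum of all cells (camera adjusted p = 2.07e-24 and 3.78e-10, and adjusted p = 0.160 and 0.555 with an estimated correlation). It was past the threshold without LOM612 replicate 2 (adjusted p = 0.0470) and with the halved and common UMI minimums (0.0397 and 0.0426), but not with the doubled one, and without DMSO replicate 2 the class past it was the epicardial-like cells (adjusted p = 0.0487). The share of cardiomyocyte-like cells differed by -1.07 percentage points between LOM612 and DMSO, and without DMSO replicate 1 by 0.606 points. For endothelial-like cells the difference was 0.0212 points, and -0.205 without LOM612 replicate 2. Clusters within a class were not tested for their share. Cardiomyocyte-like cluster 4 held 570 and 487 cells with DMSO and 704 and 579 with LOM612. The whole cardiomyocyte-like class held 2691 and 2190 cells with DMSO and 2133 and 1634 with LOM612.

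In cardiomyocyte-like cells, transcripts of the hypoxia response and glycolysis lists were higher with LOM612, and those of the S phase and cholesterol synthesis lists lower, by camera with its preset correlation. With an estimated correlation none of the 4 lists passed (adjusted p = 0.229, 0.229, 0.229 and 0.420). That test has few degrees of freedom here and its power was not checked, so it does not decide whether the lists changed. BHLHE40, a transcriptional repressor induced by low oxygen (ENSG00000134107, chromosome 3, 4979116 to 4985323), rose by 2.33 ± 0.090 on the log2 scale (SE, n = 2 libraries per group; adjusted p = 9.86e-14). Its level went from 4.5 to 22.6 CPM, UMI counts scaled to a common library total. NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022) rose by 1.91 ± 0.10 (adjusted p = 3.13e-08), and SLC2A1, the glucose transporter GLUT1 (ENSG00000117394, chromosome 1, 42925375 to 42959176), by 1.5 ± 0.063, from 59.7 ± 4.40 to 169 ± 7.17 CPM (SD, n = 2). DDIT4, an inhibitor of mTOR signalling (ENSG00000168209, chromosome 10, 72273920 to 72276036), rose by 1.29 ± 0.057. TXNIP, an inhibitor of glucose uptake whose transcript glucose is known to induce (ENSG00000265972, chromosome 1, 145992435 to 145996600), went from 509 ± 37.9 to 230 ± 14.4 CPM (log2 -1.15 ± 0.069, adjusted p = 2.01e-10), and its relative ARRDC4 (ENSG00000140450, chromosome 15, 97960698 to 97973838) changed by -1.51 ± 0.10. Coordinates are on GRCh38 and span whole protein-coding genes of GENCODE release 29.

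Over all 18708 genes tested in cardiomyocyte-like cells, 2881 changed, 1574 upwards and 1307 downwards, and 251 of them by a log2 fold change of at least 1. Among annotated genes at 10 CPM or more, the other large rises were in ANKRD37 (1.57), EPS8L2 (1.48), the neuronal enolase ENO2 (1.44), STC2 (1.24) and MTFP1 (1.24). HIF1A-AS3 (1.36) lies antisense to HIF1A, so its counts are uncertain. The large falls besides ARRDC4 and TXNIP were in RRM2, a subunit of ribonucleotide reductase (-1.25 ± 0.11), the replication checkpoint gene CLSPN (-1.23 ± 0.10), GUCY1A2 (-1.15) and MYBL2 (-1.10). TAGLN (-0.96 ± 0.059), TMSB15A (-0.93), KLF10 (-0.90) and MCM7 (-0.87) followed. TAGLN and GUCY1A2 did not fall in every part of the class: within cardiomyocyte-like cluster 4 alone their log2 changes were 0.55 and 0.33. The calls of RRM2 and CLSPN ended in G1 cells (-0.11 and -0.68, adjusted p = 0.848 and 0.302), in cluster 0 alone (-0.22 and -0.61, adjusted p = 0.731 and 0.0605) and in cluster 7 alone (-0.54 and -0.45, adjusted p = 0.716 and 0.808). The count of changed genes was 1622 without LOM612 replicate 1, 1596 without LOM612 replicate 2 and 1350 by DESeq2's Wald test, and 563 passed a test against a change of 1.2-fold.

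Transcripts of the FOXO factors themselves did not pass in cardiomyocyte-like cells. FOXO1 (ENSG00000150907, chromosome 13, 40469953 to 40666597) was at 18.1 CPM with DMSO and 17.5 with LOM612 (log2 -0.045 ± 0.077, adjusted p = 0.752), and FOXO3 (ENSG00000118689, chromosome 6, 108559835 to 108684774) at 39.1 and 40.5 (log2 0.054 ± 0.065, adjusted p = 0.638). FOXO4 gave -0.10 ± 0.12 (adjusted p = 0.617) and FOXO6 0.33 ± 0.17 (adjusted p = 0.221). The log2 value of FOXO3 was -0.030 without DMSO replicate 1, and that of FOXO1 was 0.029 without DMSO replicate 2. Transcript levels do not show where the proteins were in the cell. As a list, the FOXO family did not pass (0 of 4 measured members rose, 0 fell and 4 did not pass, with the same counts adjusted over the list alone; median 0.0044, camera adjusted p = 0.865), with a median of -0.073 without DMSO replicate 1. Among FOXO target genes, 4 of 34 measured members rose, 2 fell and 28 did not pass, with the same counts adjusted over the list alone, and the list did not pass (median 0.027, camera adjusted p = 0.562). BNIP3, a mitophagy receptor, rose by 0.86 and the insulin receptor substrate IRS2 by 0.64 (its call ended in clusters 0 and 7 alone, at 0.23 and 0.39, adjusted p = 0.197 and 0.892), whereas TXNIP and SESN3, a stress-induced sestrin, changed by -1.15 and -0.40. FOXM1, a proliferation factor, gave -0.53 ± 0.37 (adjusted p = 0.481), with adjusted p = 6.01e-04 without DMSO replicate 2 and 4.49e-05 without LOM612 replicate 2.

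Genes of the hypoxia response list, known to be induced through HIF factors, rose together: 20 of 21 measured members rose, 0 fell and 1 did not pass, with the same counts adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 9.39e-87, and adjusted p = 0.229 with an estimated correlation). Besides NDRG1, ANKRD37, SLC2A1 and DDIT4, HILPDA rose by 0.92 and BNIP3 by 0.86. Glycolysis genes rose with them: 16 of 24 measured members rose, 0 fell and 8 did not pass, with 19 up and 0 down adjusted over the list alone (median log2 fold change 0.36, camera adjusted p = 2.33e-37, and adjusted p = 0.229 with an estimated correlation). Hexokinase HK2 rose by 1.17, the lactate exporter SLC16A3 by 0.78 and lactate dehydrogenase LDHA by 0.75. SLC2A1, ALDOC, PFKFB4 and PDK1 belong to both lists, so the lists are not separate evidence, and of these genes PDK1 alone did not pass. Both lists were higher within each cardiomyocyte-like cluster, by medians of 0.23, 1.19 and 0.89 (hypoxia) and 0.061, 0.80 and 0.30 (glycolysis) in clusters 0, 4 and 7. Genes that differed between groups were not taken out before clustering. Cluster 0 held most cardiomyocyte-like cells in each library, with 1803, 1531, 1309 and 968 cells in DMSO replicates 1 and 2 and LOM612 replicates 1 and 2, and cluster 4 held 570, 487, 704 and 579. The class as a whole held fewer cells with LOM612, so cluster 4 made up a larger part of it there. Both lists also passed a directional test that does not compare them with other genes (fry, adjusted p = 0.0439 and 0.0382).

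**Figure D1:**
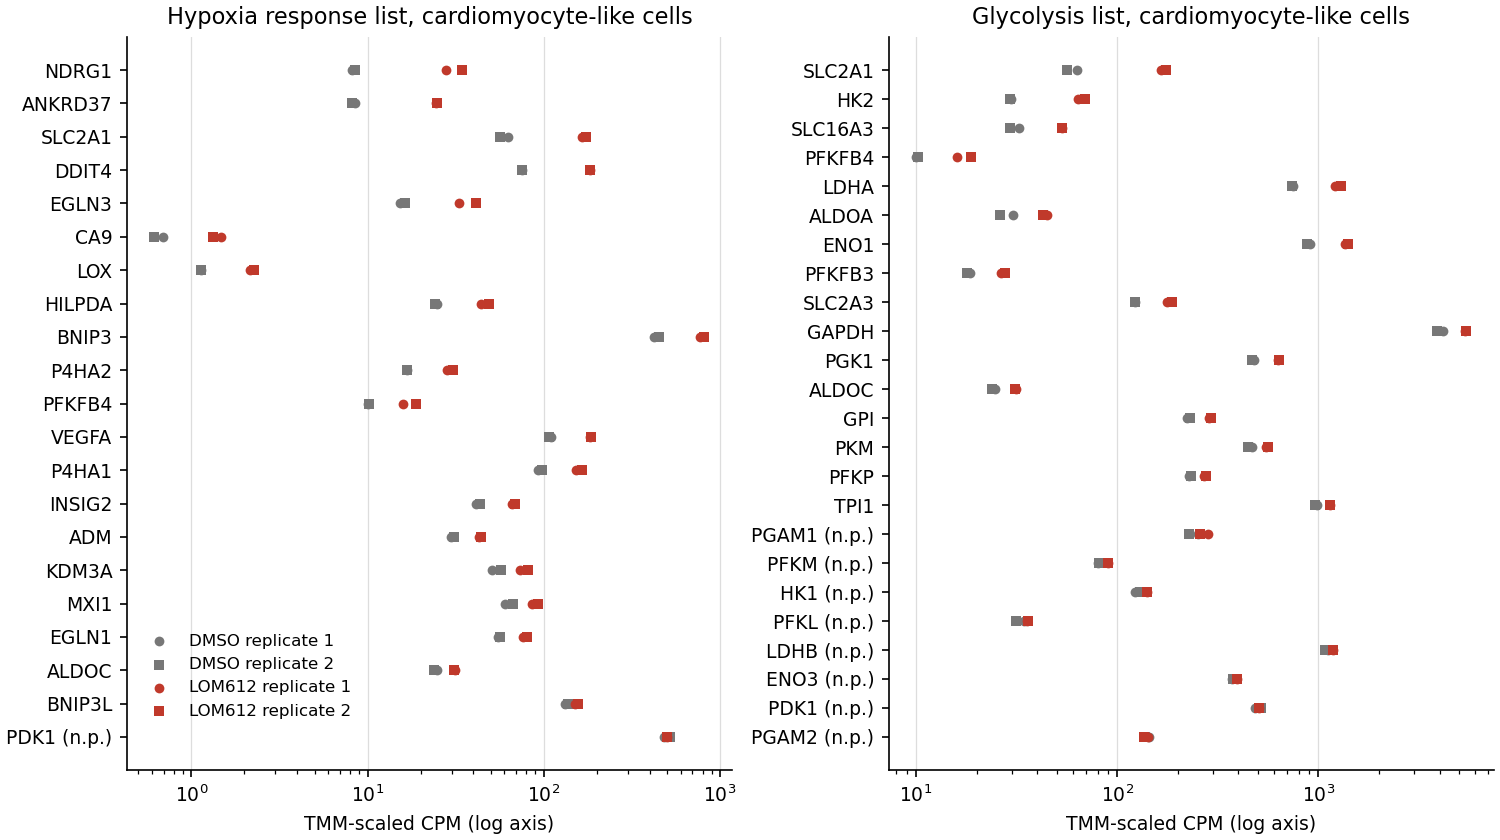
Level of each gene of the hypoxia response list (left) and the glycolysis list (right) in cardiomyocyte-like cells, as CPM scaled by TMM on a log axis. Each point is 1 library, with circles for replicate 1 and squares for replicate 2, grey for DMSO and red for LOM612, and (n.p.) marks genes that did not pass the test. SLC2A1 stood at 59.7 CPM on average with DMSO and at 169 with LOM612, and both LOM612 libraries lay above both DMSO libraries for each gene that passed.

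Genes of DNA replication and of division were lower as lists in cardiomyocyte-like cells by camera with its preset correlation. Many genes of replication passed singly, and few of division. In the S phase list, 0 of 43 measured members rose, 30 fell and 13 did not pass, with 0 up and 31 down adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 2.27e-27, and adjusted p = 0.229 with an estimated correlation). Besides RRM2 and CLSPN, the helicase HELLS changed by -0.63 and the replication licensing factor MCM6 by -0.67. MCM7, named above, is not in this list. In the G2 and M phase list, 0 of 54 measured members rose, 5 fell and 49 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 1.60e-09, and adjusted p = 0.586 with an estimated correlation), with LBR at -0.51 and JPT1 at -0.35. FOXM1 target genes were lower as a list, although few members passed: 0 of 17 measured members rose, 2 fell and 15 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 0.00106, and adjusted p = 0.646 with an estimated correlation). That call ended without DMSO replicate 1 (adjusted p = 0.113) and without LOM612 replicate 1 (adjusted p = 0.188). SKP2, an F-box protein of G1 to S transition, changed by -0.25 (adjusted p = 0.184 without LOM612 replicate 2), and CKS1B by -0.22, past the threshold neither without DMSO replicate 1 (adjusted p = 0.152) nor without LOM612 replicate 1 (0.268). CKS1B turned in direction in clusters 0, 4 and 7 alone (0.074, 0.10 and 0.24) and in G1 cells (0.13), none of them past the threshold. Within cluster 7, the cycling cardiomyocyte-like cluster, the G2 and M phase and FOXM1 target lists passed camera upwards at its preset correlation. Their medians there were 0.44 and 0.47 (camera adjusted p = 2.04e-14 and 7.82e-08). In the whole class the estimated correlation of both lists was 0.77. Cells of cluster 7 called as cycling were 78.0% and 97.7% in DMSO replicates 1 and 2, and 87.5% and 98.9% in LOM612 replicates 1 and 2. In cluster 4 alone the S phase, G2 and M phase and FOXM1 target lists did not pass (adjusted p = 0.544, 0.0937 and 0.474).

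Fewer cardiomyocyte-like cells were called as cycling after LOM612. After thinning every cell to 7000 UMIs, which left out no cell, 11.1% and 9.59% were called in S or G2/M phase with DMSO and 5.72% and 6.12% with LOM612. The means were 10.4% ± 1.08 and 5.92% ± 0.283 (SD, n = 2), a difference of -4.43 percentage points. The log2 ratio was -0.82 ± 0.11 (SE) in edgeR's test of cell numbers, with adjusted p = 0.0361 over 7 classes, while the exact 2-sided permutation test gave p = 0.333, its smallest possible value. Without thinning the difference was -4.41 points. The share was lower in 15 of 15 alternatives, 1 of which took all cells in place of cardiomyocyte-like cells, but the edgeR call ended in 7 of them. These were the fits without DMSO replicates 1 and 2 (adjusted p = 0.115 and 0.0656), without LOM612 replicates 1 and 2 (0.0770 and 0.0641) and with the replicate number as a block (0.0655), the doubled UMI minimum (0.0964) and a count of cells with an MKI67 or TOP2A UMI (0.105). The upper estimate of free RNA in cardiomyocyte-like cells, which phase calls also read, was 3.41% and 2.68% of UMIs with DMSO and 2.72% and 2.46% with LOM612. Among epicardial-like cells 3.83% and 1.99% were called as cycling, which did not pass (adjusted p = 0.0623), and among endoderm or hepatocyte-like cells 17.0% and 17.4% (adjusted p = 0.958).

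**Figure D2:**
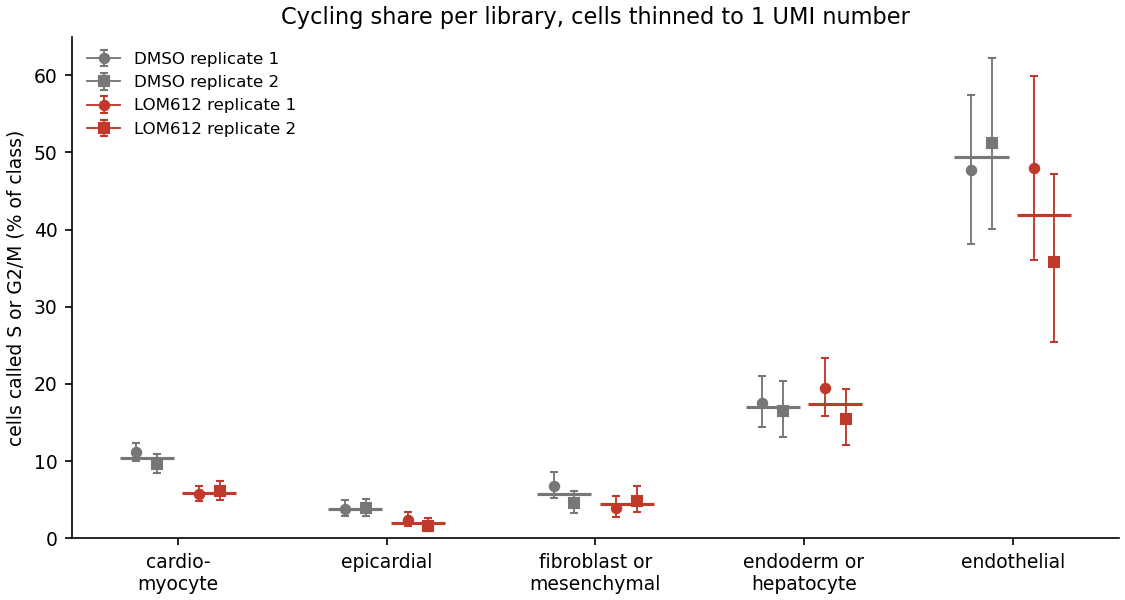
Percentage of cells called in S or G2/M phase after thinning to 7000 UMIs per cell, in 5 cell classes. Each point is 1 library with its exact 95% binomial interval, which covers counting error only, and horizontal lines are group means. In cardiomyocyte-like cells the means were 10.4% with DMSO and 5.92% with LOM612, while in endoderm or hepatocyte-like cells they were 17.0% and 17.4%.

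Sarcomere and fetal-enriched cardiomyocyte transcripts were lower. In the sarcomere list, 0 of 27 measured members rose, 7 fell and 20 did not pass, with 1 up and 9 down adjusted over the list alone (median log2 fold change -0.14, camera adjusted p = 1.08e-05, and adjusted p = 0.420 with an estimated correlation), with the M-band gene MYOM1 at -0.41, troponin C TNNC1 at -0.44 and the thick-filament gene MYBPC3 at -0.29 (adjusted p = 0.108 without LOM612 replicate 2). Cluster 4 went the other way for this list, with a median of 0.20 (adjusted p = 2.26e-08 by camera at its preset correlation). There TNNC1 and MYBPC3 stood at 0.14 and 0.061. For fetal-enriched cardiomyocyte genes, 1 of 13 measured members rose, 6 fell and 6 did not pass, with 2 up and 7 down adjusted over the list alone (median log2 fold change -0.18, camera adjusted p = 7.40e-07, and adjusted p = 0.229 with an estimated correlation). They included the smooth muscle actin ACTA2 (-0.59) and CALD1 (-0.40). Adult-enriched cardiomyocyte genes moved both ways, the muscle creatine kinase CKM rising by 0.42 and COX6A2 by 0.36, and CACNA1C and CAVIN4 changing by -0.45 and -0.67. In that list, 9 of 26 measured members rose, 4 fell and 13 did not pass, with 10 up and 7 down adjusted over the list alone, and it did not pass (median 0.023, mean -0.046, adjusted p = 0.833).

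Calcium handling and ion channel genes did not pass as lists. For calcium handling, 2 of 22 measured members rose, 3 fell and 17 did not pass, with 3 up and 5 down adjusted over the list alone (median -0.11, camera adjusted p = 0.0761, and 0.0109 without DMSO replicate 1), with the calcium store protein CASQ2 at -1.05 (adjusted p = 0.14 without LOM612 replicate 1). For cardiac ion channels, 1 of 19 measured members rose, 3 fell and 15 did not pass, with the same counts adjusted over the list alone (median -0.10, camera adjusted p = 0.159), with the potassium channel KCNQ1 at 0.43 (adjusted p = 0.0711 without LOM612 replicate 1). Among ventricular markers, 2 of 8 measured members rose, 1 fell and 5 did not pass, with 3 up and 2 down adjusted over the list alone (median -0.014, mean -0.13, test direction upwards, adjusted p = 0.862), with the transcription factor IRX3 rising by 0.50. Atrial markers were lower: 1 of 12 measured members rose, 4 fell and 7 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.00694, and adjusted p = 0.563 with an estimated correlation). That call ended without LOM612 replicate 2 (adjusted p = 0.108), as did that of the atrial factor NR2F2 at -0.31 (adjusted p = 0.0715). Sinoatrial node markers were lower as a list: 0 of 8 measured members rose, 2 fell and 6 did not pass, with 0 up and 3 down adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 0.00396, and adjusted p = 0.420 with an estimated correlation), with VSNL1 at -0.56.

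Transcripts encoded in mitochondrial DNA were lower: 0 of 13 measured members rose, 9 fell and 4 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.27, camera adjusted p = 1.69e-08, and adjusted p = 0.420 with an estimated correlation). MT-ND1 changed by -0.44, MT-ND3 by -0.46 and MT-ND6 by -0.42, beside the lower mitochondrial share of UMIs per cell. Nuclear genes of oxidative phosphorylation did not pass as a list: 11 of 77 measured members rose, 2 fell and 64 did not pass, with the same counts adjusted over the list alone (median 0.025, camera adjusted p = 0.145). It passed camera upwards at the preset correlation without DMSO replicate 1 (median 0.078) and without LOM612 replicate 2 (0.060). Without DMSO replicate 2 and without LOM612 replicate 1 its medians were -0.011 and -0.0079. Over all libraries its estimated correlation was 0.713, and camera with that gave adjusted p = 0.926. SDHD, a subunit of succinate dehydrogenase, was at 0.31 (adjusted p = 0.0541 without LOM612 replicate 1). For fatty acid oxidation, 4 of 38 measured members rose, 1 fell and 33 did not pass, with the same counts adjusted over the list alone (median 0.035, camera adjusted p = 0.145), and the lipid droplet protein PLIN2 rose by 0.70 and ACADS by 0.36.

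Cholesterol synthesis genes were lower: 1 of 24 measured members rose, 12 fell and 11 did not pass, with 1 up and 14 down adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 6.07e-11, and adjusted p = 0.420 with an estimated correlation). ACAT2 changed by -0.58, HMGCS1 by -0.51 and IDI1 by -0.50. Fatty acid synthesis did not pass as a list: 1 of 15 measured members rose, 3 fell and 11 did not pass, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.166), with the regulator SREBF1 rising by 0.72 and ACLY at -0.42. Heat shock genes were lower: 0 of 16 measured members rose, 9 fell and 7 did not pass, with 0 up and 10 down adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 2.36e-07, and adjusted p = 0.229 with an estimated correlation). The chaperone genes DNAJB1 and HSPA8 changed by -0.48 and -0.39, and HSPA1A and HSPA1B, near-identical copies whose counts are uncertain, by -0.79 and -0.80. Endoplasmic reticulum chaperones did not pass: 0 of 20 measured members rose, 4 fell and 16 did not pass, with the same counts adjusted over the list alone (median -0.048, camera adjusted p = 0.0983, and 0.0243 without DMSO replicate 2), although the calcium-binding chaperone CALR changed by -0.38 and SDF2L1 by -0.42.

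The amino acid response list of ATF4 targets rose: 8 of 27 measured members rose, 2 fell and 17 did not pass, with 10 up and 2 down adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 2.78e-06, and adjusted p = 0.420 with an estimated correlation). STC2, DDIT4, the stress factor DDIT3 (0.96) and CEBPB (0.58) were among its risers. The call of the ATF4 list ended in cluster 0 alone (adjusted p = 0.0584). The NRF2 oxidative stress list was higher: 7 of 25 measured members rose, 1 fell and 17 did not pass, with 9 up and 1 down adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.00506, and adjusted p = 0.420 with an estimated correlation). Settings that ended its call included cluster 4 alone, the fit without DMSO replicate 2 (median 0.11) and subtraction of the estimated free RNA. NQO1, a quinone reductase, rose by 0.80, or 0.63 after that subtraction, and AKR1C2 by 0.74, or 0.39 with the call lost. In clusters 4 and 7 alone the NQO1 call ended (0.54 and 0.37, edgeR adjusted p = 0.112 and 0.961). In cluster 7 alone that of AKR1C2 ended too (1.15, edgeR adjusted p = 0.487). SQSTM1 rose by 0.31 (0.048 and 0.50 in clusters 0 and 7 alone, adjusted p = 0.691 and 0.536) and the ferritin gene FTL, which has many processed copies, by 0.51. Aryl hydrocarbon receptor targets did not pass: 1 of 4 measured members rose, 0 fell and 3 did not pass, with the same counts adjusted over the list alone (median -0.13, mean 0.023, test direction upwards, adjusted p = 0.610). Nor did metallothioneins: 0 of 4 measured members rose, 2 fell and 2 did not pass, with the same counts adjusted over the list alone (median -0.17, camera adjusted p = 0.337). MT1E, 1 of a set of close copies, was at -0.68 (adjusted p = 0.104 without DMSO replicate 1 and 0.0676 without LOM612 replicate 2).

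For p53 target genes, 7 of 26 measured members rose, 3 fell and 16 did not pass, with 8 up and 3 down adjusted over the list alone (median 0.067, camera adjusted p = 0.418). Of those that fell, TP53I3 stood at -0.46 and TP53INP1 at -0.37. Of those that rose, PHLDA3 stood at 0.29 and BTG2 at 0.23. Both calls ended without LOM612 replicate 2 (0.23 and 0.21), and that of BTG2 also without LOM612 replicate 1 (0.25). Apoptosis effectors did not pass: 2 of 22 measured members rose, 2 fell and 18 did not pass, with the same counts adjusted over the list alone (median -0.045, mean 0.019, test direction upwards, adjusted p = 0.833), with CASP9 rising by 0.97 and BIK by 0.44, and APAF1 and MCL1 changing by -0.37 and -0.31 (adjusted p = 0.238 and 0.0559 without LOM612 replicate 1). Autophagy and lysosome genes did not pass: 4 of 25 measured members rose, 2 fell and 19 did not pass, with 5 up and 3 down adjusted over the list alone (median 0.021, camera adjusted p = 0.130, and 0.0492 without DMSO replicate 1), with the protease CTSB at 0.30. In the list of PI3K-AKT and insulin signalling, 3 of 23 measured members rose, 1 fell and 19 did not pass, with 3 up and 2 down adjusted over the list alone (median -0.044, camera adjusted p = 0.956), and IGFBP2 rose by 0.62. Cytosolic ribosomal proteins did not pass: 0 of 75 measured members rose, 1 fell and 74 did not pass, with 0 up and 0 down adjusted over the list alone (median -0.019, camera adjusted p = 0.450). That list passed camera downwards at the preset correlation without DMSO replicate 2 (median -0.064) and without LOM612 replicate 1 (-0.064). Without DMSO replicate 1 and without LOM612 replicate 2 its medians were 0.047 and 0.021. Over all libraries the list's estimated correlation was 0.651, and camera with that gave adjusted p = 0.928. Many of its members have near-identical copies.

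Extracellular matrix genes were lower as a list: 1 of 29 measured members rose, 6 fell and 22 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 8.78e-04, and adjusted p = 0.420 with an estimated correlation). The call ended without DMSO replicate 1 (adjusted p = 0.0552). Collagen genes COL5A2 and COL6A3 changed by -0.54 and -1.74 (the COL6A3 call ended with the automatic doublet limit and in cluster 7 alone, adjusted p = 0.115 and 0.209), and the collagen crosslinker LOX, also in the hypoxia list, rose by 0.95, but stood at -0.10 in cluster 0 alone. WNT response genes were lower: 0 of 15 measured members rose, 3 fell and 12 did not pass, with 0 up and 4 down adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.0236, and adjusted p = 0.420 with an estimated correlation), with CCND2 at -0.57. Without LOM612 replicate 2 that list gave adjusted p = 0.118. The TGF-beta response did not pass: 3 of 17 measured members rose, 2 fell and 12 did not pass, with 4 up and 3 down adjusted over the list alone (median 0.0077, mean -0.19, test direction downwards, adjusted p = 0.0700, and 0.00338 without DMSO replicate 2), with TGFB1 rising by 0.42 and PMEPA1 by 0.38.

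Natriuretic and stretch response genes did not pass: 2 of 9 measured members rose, 0 fell and 7 did not pass, with 2 up and 1 down adjusted over the list alone (median 0.029, mean -0.26, test direction upwards, adjusted p = 0.294), with FHL2 rising by 0.55. Immediate early and dissociation genes, which cell dissociation can induce, did not pass: 4 of 18 measured members rose, 1 fell and 13 did not pass, with 5 up and 1 down adjusted over the list alone (median -0.048, mean -0.021, test direction upwards, adjusted p = 0.833). FOS stood at 0.33, but turned in direction in cluster 7 alone, and KLF6 stood at -0.35. Interferon and inflammatory response genes did not pass: 2 of 17 measured members rose, 5 fell and 10 did not pass, with 4 up and 5 down adjusted over the list alone (median -0.039, mean -0.29, adjusted p = 0.153, and 0.00807 without DMSO replicate 2). IFI6 and IFIT1 changed by -0.70 and -0.52. In all, 16 of the 37 lists passed camera, 4 upwards and 12 downwards, and with an estimated correlation 0 passed, 5 having an unadjusted p under 0.05. The directional fry test, which does not compare a list with other genes, passed 3. In cluster 4 alone 7 of the 16 camera calls were kept, the sarcomere list turned, and the calls ended for the S phase, G2 and M phase, FOXM1 target, fetal-enriched, cholesterol synthesis, heat shock, NRF2 and extracellular matrix lists. Cluster 0 alone kept 15 and cluster 7 alone 12.

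Summed over all cells, GPX2, a glutathione peroxidase (ENSG00000176153, chromosome 14, 64939152 to 64942905), rose by 4.12 ± 0.10 on the log2 scale, from 0.788 ± 0.151 to 13.9 ± 0.639 CPM (SD, n = 2; adjusted p = 5.98e-20). AKR1C2, an aldo-keto reductase with near-identical relatives (ENSG00000151632, chromosome 10, 4987400 to 5018031), rose by 3.19 ± 0.058 and NQO1 (ENSG00000181019, chromosome 16, 69706996 to 69726951) by 2.19 ± 0.056. ALDH1L1 rose by 1.78 and the globin HBD by 2.08, but HBD passed neither without LOM612 replicate 1 (adjusted p = 0.223) nor without LOM612 replicate 2 (0.243). CALB1 changed by -1.97, ACTA2 by -0.78, the interferon-induced IFIT1 and IFI6 by -0.77 and -0.75, and HSPA1A by -0.74. FOXO6 rose by 0.51 ± 0.083 (adjusted p = 4.87e-05), and FOXM1 changed by -0.38 ± 0.11 (adjusted p = 0.0417, and 0.0840 without LOM612 replicate 1). With the replicate number as a block the calls of CALB1, HBD and FOXM1 ended (adjusted p = 0.157, 0.0865 and 0.204). FOXO1, FOXO3 and FOXO4 did not pass (-0.075, -0.042 and -0.15). Of 22615 genes, 5984 changed, 3216 upwards and 2768 downwards. Without LOM612 replicate 2 the count was 3815, by DESeq2's Wald test 3649, with cells thinned to equal depth 3694, and against a 1.2-fold change 923. These sums mix cell classes.

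Hypoxia response and glycolysis genes rose as lists in each other named class by camera with its preset correlation, and with an estimated correlation neither list passed in any of these 4 classes. In epicardial-like cells SLC2A1 rose by 1.25 ± 0.051, LDHA by 1.09 ± 0.042, DDIT4 by 0.92 and the collagen hydroxylase P4HA1 by 0.85, and LRRC17 changed by -0.86. In fibroblast or mesenchymal-like cells SLC2A1 rose by 2.00 ± 0.10, BNIP3 by 1.36 ± 0.061, LDHA by 1.22, P4HA1 by 1.08 and DDIT4 by 0.96. In endothelial-like cells the lipase inhibitor ANGPTL4 rose by 2.68 ± 0.23, DDIT4 by 2.15 ± 0.14, STC1 by 1.57 and FTL by 0.60, and TXNIP changed by -1.41. Hypoxia response members that rose were 13 of 21 in epicardial-like cells (median 0.48, camera adjusted p = 7.65e-51, and adjusted p = 0.364 with an estimated correlation) and 15 of 21 in fibroblast or mesenchymal-like cells (median 0.43, camera adjusted p = 1.96e-51, and adjusted p = 0.210 with an estimated correlation). The same list had 15 of 21 members rising in endoderm or hepatocyte-like cells (median 0.55, camera adjusted p = 5.18e-20, and adjusted p = 0.0836 with an estimated correlation) and 9 of 19 in endothelial-like cells (median 0.78, camera adjusted p = 8.45e-36, and adjusted p = 0.490 with an estimated correlation). Glycolysis members that rose were 18 of 24, 15 of 24, 18 of 24 and 7 of 23 in the epicardial-like, fibroblast or mesenchymal-like, endoderm or hepatocyte-like and endothelial-like cells. Their camera adjusted p were 6.13e-49, 6.29e-37, 5.28e-27 and 6.52e-19, and adjusted p = 0.364, 0.178, 0.0797 and 0.490 with an estimated correlation.

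In endoderm or hepatocyte-like cells, aldo-keto reductases and other NRF2 list members rose. AKR1C2 rose by 3.42 ± 0.060 (36.3 ± 2.22 to 390 ± 8.08 CPM, SD, n = 2), GPX2 by 3.91 ± 0.088, NQO1 by 2.61 ± 0.064 and AKR1B10 by 5.72 ± 0.16, while TXNIP changed by -2.46 ± 0.068. The AKR genes have close relatives, and their counts are uncertain. NRF2 oxidative stress members that rose were 22 of 25 (median 1.25, camera adjusted p = 3.12e-165, and adjusted p = 0.0797 with an estimated correlation), and ATF4 amino acid response members 20 of 28 (median 0.82, camera adjusted p = 2.79e-34, and adjusted p = 0.0797 with an estimated correlation). Of 16040 genes tested there 3591 changed, 1978 upwards and 1613 downwards. In the remaining classes 2178 of 16964 genes changed in epicardial-like, 1649 of 15742 in fibroblast or mesenchymal-like and 216 of 11051 in endothelial-like cells. The fibroblast or mesenchymal-like count was 884 and 842 without DMSO replicates 1 and 2, and 1004 and 801 without LOM612 replicates 1 and 2. The endothelial-like count was 338 with no filter on low counts.

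**Figure D3:**
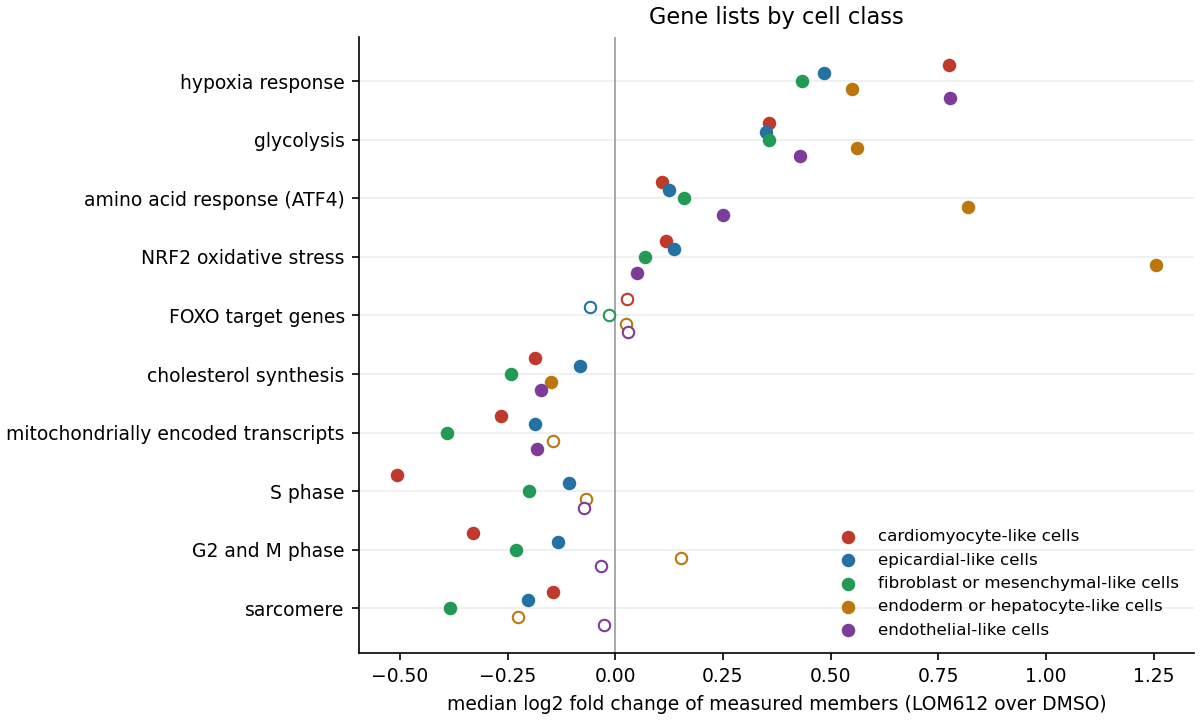
Median log2 fold change (LOM612 against DMSO, 2 libraries each) of 10 gene lists in 5 cell classes. Filled points passed camera with its preset correlation and open points did not. Hypoxia response medians lay between 0.43 and 0.78 in the 5 classes, while the NRF2 oxidative stress median was 1.25 in endoderm or hepatocyte-like cells and 0.12 in cardiomyocyte-like cells.

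Whether a gene responded differently in cardiomyocyte-like cells was tested directly against the sum of the other named classes. That sum mixes classes, so a difference from it can rest on 1 of them or on their mix. The difference test was not repeated with free RNA subtracted, which lowered the rise of AKR1C2 in cardiomyocyte-like cells from 0.74 to 0.39. The 5 genes with the lowest adjusted p included the aldo-keto reductases AKR1C2 and AKR1C1, whose log2 change was higher in the other cells by 2.64 ± 0.11 and 2.07 ± 0.081. TXNRD1, a thioredoxin reductase, differed by 0.87 ± 0.061, FREM2 by 0.85 ± 0.059 and fibronectin FN1 by 0.76 ± 0.055. In all 635 of 21085 genes differed, 370 with a higher and 265 with a lower change in the other cells. That count was 2066 without DMSO replicate 2, 123 without LOM612 replicate 1, 200 without LOM612 replicate 2 and 1254 with no filter on low counts. Against endoderm or hepatocyte-like cells alone 1560 genes differed, and the NRF2 list's change was higher there than in cardiomyocyte-like cells by a median of 1.01 (camera adjusted p = 2.60e-25, and adjusted p = 0.703 with an estimated correlation).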

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

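The comparisons of cardiomyocyte-like cells with each single class were chosen after the data were seen.

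Whether the change with LOM612 differed between cell classes was tested itself, with edgeR and each library as a block. It differed for 635 genes between cardiomyocyte-like cells and all other named cells, and for 596, 351, 1560 and 71 genes against epicardial-like, fibroblast or mesenchymal-like, endoderm or hepatocyte-like and endothelial-like cells. The classes differ in cells and UMIs, so these counts give no order of the classes. The sum of all other named cells mixes classes, so a difference from it can rest on 1 of them or on their mix. The log2 change of AKR1C2 was higher in the other named cells by 2.64, of AKR1C1 by 2.07, of TXNRD1 by 0.87, of FREM2 by 0.85 and of FN1 by 0.76. For the NRF2 list the change was higher in endoderm or hepatocyte-like than in cardiomyocyte-like cells by a median of 1.01 (camera adjusted p = 2.60e-25, and adjusted p = 0.703 with an estimated correlation).

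NRF2-linked genes rose more in endoderm or hepatocyte-like than in cardiomyocyte-like cells by camera, a difference that did not pass with an estimated correlation (adjusted p = 0.703). A shift between subclusters was argued against, because the list's median within the largest subcluster was 1.24 (camera adjusted p = 8.40e-129, and adjusted p = 0.0546 with an estimated correlation) against 1.25 in the whole class, a ratio of 0.991. That subcluster held 446 and 367 of the class's 535 and 430 cells with DMSO, and 362 and 328 of 443 and 414 with LOM612. The ratio therefore compares largely the same cells, and a shift within that subcluster was not tested. Free RNA from other classes was argued against too, since the median was 1.28 after its subtraction, a ratio of 1.02. What stays open is a shift within the largest subcluster, a difference in handling between wells and, as a hypothesis, that LOM612 may induce NRF2-linked genes more in these cells. No test here separates these.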

How the results depend on the processing

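The automatic doublet limit, the common UMI minimum, the subtraction of free RNA, each cardiomyocyte-like cluster alone and each other class against cardiomyocyte-like cells were chosen after the data were seen. Over 5191 comparisons of 236 results with an alternative, 4536 kept the direction and the side of the threshold, or for counts stayed within 1.5 times. In 457 comparisons a call was lost, in 69 gained, in 31 a count moved further, and in 98 the direction turned. Of these 98, 29 were with 1 library left out, and a single result can turn in several of them. The direction of a list is that of its test, so its median can keep its sign. The cause of a change was not tested, except that a fit without 1 library, a single cluster, a higher UMI minimum and thinned cells hold fewer libraries, cells or UMIs by construction. Without 1 library the lone sample of a group is assumed to vary like the others. Thinning, which lowers depth and also gives cells equal weight, called 2198 genes in cardiomyocyte-like cells, 1752 of them among the 2881, so what depth alone limits was not separated.

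Against 2881 genes changed in cardiomyocyte-like cells, DESeq2's Wald test called 1350 (1308 of them shared), the doubled UMI minimum 1387, the test against a 1.2-fold change 563, and all cells with a TNNT2 UMI, most cells of every library, 5316. Clusters 0 and 7 alone gave 1328 and 26, and leaving out 1 library 1596 to 3685. Over all cells (5984) the Wald test gave 3649, the 1.2-fold test 923, thinned cells 3694, and 1 library less 3815 to 5386. The fibroblast or mesenchymal-like count (1649) was 801 to 1004 with 1 library less, and the endothelial-like count (216) was 338 with no filter. The count of genes that differed between classes (635) was 1254 with no filter, 123 to 2066 with 1 library less, and 1560, 351 and 71 against the endoderm or hepatocyte-like, fibroblast or mesenchymal-like and endothelial-like cells. Of 16 lists past camera, 0 passed with an estimated correlation and 3 by fry, and clusters 0, 4 and 7 alone kept 15, 7 and 12.

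The number of classes whose share passed (0) was 1 with the halved and 1 with the common UMI minimum, and 0 to 1 with 1 library less. The share of endothelial-like cells turned direction with the doubled, halved and common UMI minimum and the automatic doublet limit (-0.119, -0.0224, -0.101 and -0.0161 percentage points), and was -0.205 to 0.247 with 1 library less. Fibroblast or mesenchymal-like cells stood at -1.74 points with the doubled minimum, and cardiomyocyte-like cells at -2.75 to 0.606 with 1 library less. The cycling share of cardiomyocyte-like cells was lower in 15 of 15 alternatives and kept its call in 8. The call ended with the replicate block, the doubled UMI minimum and an MKI67 or TOP2A UMI (differences of -4.43, -4.54 and -2.87 points), and without each library (-5.19 to -3.67).

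Of 124 named genes called in cardiomyocyte-like cells, 116 and 119 were kept without DMSO replicates 1 and 2, 95 and 96 without LOM612 replicates 1 and 2, 99 of 123 by DESeq2's Wald test and 59 against a 1.2-fold change. The log2 fold changes of these genes turned in direction: in cluster 0 alone CKS1B 0.074, FOXO3 -0.10 and LOX -0.10; in cluster 4 alone TAGLN 0.55, GUCY1A2 0.33, TNNC1 0.14, FOXM1 0.12, CKS1B 0.10, SLC7A5 0.091, FADS1 0.086, MYBPC3 0.061, GJA1 0.058, MT1E 0.034 and RPL35 0.0086; in cluster 7 alone MT2A 0.59, BIRC5 0.48, KIF11 0.33, FOXM1 0.31, CKS1B 0.24, TP53INP1 0.062, HAPLN1 0.048, FOXO1 0.038, JPT1 0.027, FOXO3 -0.067 and FOS -0.39. In cells with a TNNT2 UMI they were CYP1B1 0.38, SLC7A5 0.10, RPS6 0.024, RPL35 0.023, FOXO3 -0.033 and MT1X -0.18, in G1 cells CKS1B 0.13 and MT2A 0.073, with the doubled UMI minimum MT1X -0.17 and MT2A 0.0012, with thinned cells FOXO1 0.066 and FHL1 0.029, and with free RNA subtracted MT2A 0.044. With 1 library less, ranges that crossed 0 were -0.12 to 0.029 (FOXO1), -0.030 to 0.14 (FOXO3), -0.47 to 0.59 (MT2A) and -0.052 to 0.45 (MT1X). Over all cells FOXO1 was 0.0084 with thinned cells, and FOXO3 -0.10 to 0.0059 with 1 library less.

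Lists turned the direction of their test, with these medians. In cluster 0 alone they were FOXO family -0.058, FOXO targets -0.020, adult-enriched -0.076, immediate early -0.048, apoptosis -0.0067 and p53 -0.0014. In cluster 4 alone they were sarcomere 0.20, ribosomal proteins 0.079 and PI3K-AKT -0.018. In cluster 7 alone they were FOXM1 targets 0.47, G2 and M 0.44, immediate early -0.23, adult-enriched -0.063, metallothioneins 0.046, nuclear oxidative phosphorylation -0.018, FOXO family -0.015 and ventricular 0.0054. PI3K-AKT was -0.035 with the doubled UMI minimum, -0.045 with free RNA subtracted and -0.044 by fry, immediate early -0.074 with the doubled minimum, and ventricular -0.046 with the common minimum and -0.050 with doublets kept. With 1 library less, lists that turned had medians of -0.073 to 0.084 (FOXO family), 0.0018 to 0.029 (adult-enriched), -0.064 to 0.047 (ribosomal proteins), -0.12 to 0.048 (immediate early), -0.019 to 0.072 (natriuretic), -0.011 to 0.078 (nuclear oxidative phosphorylation), 0.032 to 0.20 (p53), -0.074 to -0.016 (PI3K-AKT), -0.11 to -0.015 (apoptosis) and -0.12 to 0.064 (ventricular).

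Both groups carry the replicate numbers 1 and 2, and no label gives same-numbered libraries a shared source. Across genes, the differences between replicates 1 and 2 correlated between the groups with r = 0.346 in cardiomyocyte-like cells and 0.219 over all cells, with genes not being independent replicates. With the replicate number as a block, 4428 genes changed in cardiomyocyte-like cells (2879 of the 2881 among them) and 7122 over all cells. The block gave 2910, 2039, 4264 and 279 genes in epicardial-like, fibroblast or mesenchymal-like, endoderm or hepatocyte-like and endothelial-like cells, and kept 16 of 16 lists, 123 of 124 named genes in cardiomyocyte-like cells and 9 of 12 over all cells. Test directions turned under the block for apoptosis effectors (-0.044) and ventricular markers (-0.012).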

Other observations

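The tests of sequencing depth and of cycling cells outside the cardiomyocyte-like class and within its clusters were chosen after the results were seen, as were the genes named in the next paragraphs.

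In endoderm or hepatocyte-like cells more of the redox and amino acid stress genes rose than those named so far. The thioredoxin reductase TXNRD1 rose by 1.80 ± 0.057 on the log2 scale (SE, n = 2 libraries per group), sulfiredoxin SRXN1 by 2.75 ± 0.13 and GCLM, a subunit of the first enzyme of glutathione synthesis, by 1.13 ± 0.074, while heme oxygenase HMOX1, another NRF2 target, stood at -0.051 ± 0.10 (edgeR adjusted p = 0.770). Asparagine synthetase ASNS rose by 1.73 and the pseudokinase TRIB3 by 1.77, both ATF4 targets with under 2 CPM in DMSO. Aryl hydrocarbon receptor targets rose in 3 of 4 measured members, also 3 adjusted over the list alone (median 0.82, camera adjusted p = 3.05e-14, and adjusted p = 0.111 with an estimated correlation), with CYP1A1 at 1.02 ± 0.20. This list shares NQO1 with the NRF2 list and SLC7A5 with the ATF4 list, so it is not separate evidence. TGF-beta response genes fell in 10 of 15 members and 1 rose, or 11 and 1 adjusted over the list alone (median -0.39, camera adjusted p = 8.81e-06, and adjusted p = 0.217 with an estimated correlation). The hepatocyte transcripts AFP and APOA1 fell by 0.47 and 0.30. In that class 12 of 36 lists passed camera, and 0 passed with an estimated correlation, 6 having an unadjusted p under 0.05.

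In fibroblast or mesenchymal-like cells interferon and inflammatory response genes fell in 7 of 17 measured members, or 8 adjusted over the list alone, and 1 rose (median -0.38, camera adjusted p = 3.09e-10, and adjusted p = 0.220 with an estimated correlation). The interferon-induced genes IFI6, ISG15 and IFIT1 changed by -0.94 ± 0.062, -0.74 ± 0.058 and -0.93 ± 0.12. Mitochondrially encoded transcripts fell in 10 of 13 members, or 11 adjusted over the list alone (median -0.39, camera adjusted p = 1.84e-24, and adjusted p = 0.221 with an estimated correlation), and extracellular matrix genes in 12 of 29, or 15 (median -0.19, camera adjusted p = 4.38e-08, and adjusted p = 0.244 with an estimated correlation).

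Hypoxia response and glycolysis genes rose in cardiomyocyte-like cells by camera, and with an estimated correlation neither list passed (adjusted p = 0.229 for both). Free RNA was argued against, since the hypoxia median was 0.77 before and 0.77 after its subtraction, a ratio of 0.993, and a response limited to cardiomyocytes was argued against by the list passing camera upwards in 4 other named classes. With an estimated correlation its adjusted p there were 0.364, 0.210, 0.0836 and 0.490 (epicardial-like, fibroblast or mesenchymal-like, endoderm or hepatocyte-like and endothelial-like cells), and it passed in 0 of the 4. A changed mix of clusters stays open in part: within cluster 0 the median was 0.23 (camera adjusted p = 3.54e-13, and adjusted p = 0.236 with an estimated correlation), 0.299 of that in the whole class, which lies between the limits set for this test, while clusters 4 and 7 gave medians of 1.19 and 0.89. A difference in handling between wells cannot be told apart from treatment, because it would go with treatment in both libraries of a group; the replicate number called 194 genes in a fit where treatment called 4428, which does not bear on it. A response to LOM612 stays open as a hypothesis.

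Fewer cardiomyocyte-like cells were called as cycling. Depth was argued against, since the thinned difference was 1.00 times the unthinned one, and so were doublets, since the difference was -4.09 percentage points with the doublet score limit halved, a ratio of 0.923. A change limited to cardiomyocytes was argued against, with a call that needed all 4 libraries. Among all other cells the share was 16.4% with DMSO and 12.6% with LOM612 (edgeR adjusted p = 0.0403 over 7 classes; exact permutation p = 0.333), but unnamed cluster 6 supplied 431 of 724 and 391 of 629 of these cycling cells with DMSO and 245 of 448 and 230 of 390 with LOM612. The fall had adjusted p = 0.0867, 0.0512, 0.0635 and 0.0641 without DMSO replicates 1 and 2 and LOM612 replicates 1 and 2, and 0.0827 with the replicate block. In cluster 6 the 14 cardiomyocyte markers stood at a median of 0.0331 times their CPM in cluster 7, and at 0.132 times at most, so cardiomyocytes do not make up that cluster. None of the 6 single classes tested besides cardiomyocyte-like cells passed, and epicardial-like cells had 3.83% and 1.99% (edgeR adjusted p = 0.0623) and endoderm or hepatocyte-like cells 17.0% and 17.4% (0.958). Within cardiomyocyte-like clusters 0 and 4 the shares were 2.52% and 1.14% (edgeR p = 0.000287, not adjusted; exact permutation p = 0.333, the smallest it can give) and 0.849% and 0.401% (edgeR p = 0.151, not adjusted; exact permutation p = 0.333). In cluster 7 they were 87.8% and 93.2% (edgeR p = 0.569, not adjusted; exact permutation p = 0.667), and it held 318 and 172 cells with DMSO and 120 and 87 with LOM612. A lower share of cycling cells may be a response to LOM612, and free RNA in phase calls and handling stay open.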
